A study of Mus musculus with 9 samples.

How the data were processed

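RNA expression was measured in scraped mucosa of the small intestine of male C57BL/6J mice, an inbred laboratory strain, fed for 2 weeks on diets high in fat, with palm oil (HF-PO), olive oil (HF-OO) or safflower oil (HF-SO) as the source. Per the labels, each small intestine was divided into 3 equal parts, adhering fat and pancreatic tissue were removed, RNA was extracted with TRIzol and purified on columns, and the RNA of 6 mice per diet was pooled for each part. Each of the 9 pools was labelled with biotin and hybridised to 1 Affymetrix array. Arrays of a low-fat diet were not analysed here.

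The deposited values are linear signal intensity, 1 per probe set and array, which the submitters' processing notes credit to MAS5, Affymetrix's algorithm for a single array, with no version given. The 2% trimmed mean of each array is 500, so the arrays were compared on the authors' scaling. The deposited table has 45101 probe sets, of which 64 array controls were left out and 45037 analysed, with 0 missing values. Signals ran from 0.1 to 56940, and the highest signal of an array lay between 44530 and 56940. The ratio of 3' to 5' control signals lay between 1.185 and 1.305 for beta-actin and between 0.7803 and 0.8709 for Gapdh. Detection calls were not used here.

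Probe sets were named through the platform annotation; 34945 carried 1 gene symbol, 932 several, and 9160 had no symbol there. Of those with 1 symbol, 34741 were found by their gene identifier in a RefSeq gene table, and 0 symbols changed. Where a gene had several probe sets, the brightest over the 9 arrays stood for it, which gave 18193 genes. Signals were analysed as log2(signal + 16). Probe sets whose mean over the 9 arrays was at or above the median of all probe sets, 6.80, were tested, which left 22519.

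Segments were compared with limma 3.58.1 in R 4.3.3, by a linear model with segment and diet pool as terms, empirical Bayes variances and two-sided moderated tests. The diet pool was a block because the 3 segments of a diet come from the same 6 mice. The residual, with 4 degrees of freedom, is how far the segment effect differs between the 3 pools, so it also holds any true difference of the segment effect between diets. P-values were adjusted by the Benjamini-Hochberg method over the probe sets tested, and an adjusted p under 0.05 counted as a call. A moderated F test covered all 3 segments together. Array by array, departures from the segment mean correlated across probe sets with r from -0.05 to 0.15 within a diet pool and from -0.13 to 0.05 between pools.

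Diets have 1 array per segment, and the segments of a diet share mice, so no p-value was computed for a diet. A probe set counted as set apart in a diet when its signal differed by at least 1.5-fold from both other diets in the same direction, and the gap is the log2 difference from the nearer of them. The same count was made for each diet in turn. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for these steps and for the plots.

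Gene lists, 14 of pathways and processes and 15 of cell types, were written from general knowledge before the data were examined, as were the model, the thresholds, the rule for the genes named and the alternative settings, except where another origin is stated. Lists with at least 3 tested genes, 27 of 29, were tested between SI3 and SI1 with limma's camera at a preset correlation between genes of 0.01, adjusted over the 27 lists, and again with an estimated correlation. For diets, the median over a list of HF-PO minus the mean of HF-OO and HF-SO was placed among 10000 random lists of the same size matched in 20 bins of expression, and HF-SO minus HF-OO likewise. Such a percentile describes these arrays, tests no replicates and treats the genes of a list as independent.

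Genes are named by this rule: for SI3 against SI1, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold that moved the same way in all 3 pools, and 5 each way for the other segment pairs. In each segment it also names the 10 genes set apart most each way in HF-PO and 5 each way in HF-OO and HF-SO, genes set apart the same way in all 3 segments, and any member of a list.

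The segment model was tested on simulated data with the residual spread of these arrays. It recovered 54 of 100 probe sets changed by a log2 of 1 and 11 of 100 changed by 0.5, with 6 false calls. It made 0 calls where nothing was changed. Only 200 of the 22519 probe sets were changed there, against 9969 called in the real comparison of SI3 with SI1. The Benjamini-Hochberg cutoff depends on that share, so these recovered counts do not carry over to the real data. In another simulation for diets, 97 of 100 probe sets changed by a log2 of 1 in the HF-PO array of SI3 and 22 of 100 changed by 0.5 were set apart, along with 211 unchanged ones. Its noise was the empirical Bayes residual SD of the segment model. That SD leaves out differences between pools that the segments share, so 211 may be too low. The alternatives tried were quantile normalization, centring each array on its median, a pseudocount of 1 or 64, no expression filter or a stricter one that kept the brightest probe sets, no block, an intensity trend in the variance prior, leaving out each pool, a 2-fold threshold, all probe sets of a gene, and the mean over a list. Leaving out the HF-PO array of SI1 or of SI3, and setting HF-PO against HF-OO alone or HF-SO alone, were added after the data were seen.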

Results

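The data are 9 expression arrays of mouse small-intestinal mucosa, 1 for each combination of 3 diets and 3 parts of the intestine. SI1 is the part next to the stomach, SI2 the middle and SI3 the distal part. The diets carried their fat as palm oil, olive oil or safflower oil, and their P/S values in the labels increase in that order. Each array measured RNA pooled from 6 mice, so segments were compared over 3 pools and diets over single pools. Median signals of the arrays lay between 94.4 and 105.9 and upper quartiles between 440.4 and 472.3, in units of MAS5 signal. The number of arrays limits the precision of every value.

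The comparison of SI3 with SI1 asked how expression differs between the ends of the small intestine. The largest rise was that of Fabp6, the bile acid carrier inside ileal enterocytes, whose signal was 25.1 ± 19.8 in SI1 and 53726 ± 1445 in SI3 (SD, n = 3 pools), a log2 change of 10.50 with an SE of 0.29. Slc10a2, which imports bile acids from the gut lumen, rose by 5.81 (SE 0.41), from 15.5 ± 2.03 to 1749 ± 139. Fgf15, a hormone that ileal cells release when they take up bile acids, rose by 6.55 (SE 0.38), from 7.63 ± 2.68 to 2207 ± 325. In the other direction, Akp3, an alkaline phosphatase of the duodenal brush border, fell by 8.29 (SE 0.11), from 23132 ± 3100.5 to 58.4 ± 12.2. S100g, a calcium-binding protein that vitamin D induces, fell by 7.12 (SE 0.25), from 13336 ± 1558 to 79.6 ± 10.2. Pdx1, a transcription factor of duodenum and pancreas, fell by 5.91 (SE 0.13), from 1983 ± 143 to 17.2 ± 1.85.

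Plb1, a phospholipase of the brush border, rose by 8.71 on the log2 scale from SI1 to SI3, and Slc5a8, a transporter of short-chain fatty acids and lactate, rose by 7.18. Mgat4c rose by 6.09, Tmigd1 by 5.81, Gsdmc2 by 5.19, Saa1 by 5.08, Bex1 by 4.79 and Fam151a by 4.62. The magnesium channel Trpm6 rose from 50.6 ± 12.3 to 1597 ± 325. Cpa1, Cela2a, Cpb1, Ctrl and Ctrb1, which encode digestive enzymes that the exocrine pancreas secretes, changed by -7.55, -7.43, -7.24, -5.86 and -5.62. Reg1, a secreted lectin found in pancreas and duodenum, fell by 6.90, from 33427 ± 2268 to 265.9 ± 39.5. The trypsinogen-like gene 2210010C04Rik fell by 6.09, the transcription factor Onecut2 fell by 6.04 and the proton channel Otop3 fell by 5.81. Where a signal at one end is near or below the pseudocount of 16, the size of the change depends on it: Fgf15 rose by 8.03 with a pseudocount of 1 and by 4.98 with 64, and Fabp6 by 11.61 and 9.26. Fabp6 also had the highest signal of 1 array, so saturation of its signal in SI3 was not ruled out. The adjusted p-values of all these genes from limma lay between 2.29e-07 and 7.44e-05, and each gene moved the same way in all 3 pools, which the naming rule required.

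Of 22519 probe sets, 9969 (44.3%) differed between SI3 and SI1, 5635 of them higher in SI3 and 4334 lower, and 9930 moved the same way in all 3 pools. At least 2-fold changes were seen in 823 that rose and 1267 that fell. Counted by gene, 3428 rose and 2797 fell. The median change over all probe sets tested was 0.08. Without the HF-OO pool 5551 probe sets passed, and without the HF-SO pool 6478.

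Genes for taking up and packaging fat were lower in the distal part, as shown in the plot of changes by gene list. Of 22 genes for fat uptake and chylomicron assembly, 12 fell and 1 rose, and the counts were 12 and 1 when adjusted over the list alone. The fatty acid translocase Cd36 fell by 2.07 (SE 0.13), from 2050.0 ± 369 to 488 ± 162. The acyl-CoA synthetase Slc27a2 fell by 2.13, Apoc2, an apolipoprotein that activates lipoprotein lipase, fell by 2.04 (SE 0.40), Apob fell by 1.15 and Fabp1, the liver-type fatty acid carrier, fell by 1.05. The one member that rose was Fabp2, by 0.31, while Apoa1 (0.13) and Apoa4 (-0.47) did not pass. Apoa1 had the highest signal of the array in 5 of 9 arrays, Fabp1 reached 97.0% of the highest and Fabp2 87.8%, so saturation of these signals was not ruled out. The list fell by camera with an adjusted p = 0.000494, and adjusted p = 0.411 with an estimated correlation.

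Of 31 genes for fatty acid oxidation, which include targets of the receptor PPAR alpha, 18 fell and 2 rose, and the counts were the same when adjusted over the list alone. Pdk4, a kinase that shuts glucose out of oxidation, fell by 2.45, from 1406 ± 284 to 316 ± 302, the peroxisomal thiolase Acaa1b fell by 2.20, Acot1 by 1.61 and the peroxisomal enzyme Ehhadh by 1.53. Vnn1 rose by 2.66 and Angptl4 by 0.32. The list fell with an adjusted p = 9.55e-05, and adjusted p = 0.364 with an estimated correlation.

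Sugar handling was lower in SI3 for all 9 genes of the carbohydrate list (9 also when adjusted over the list alone). The fructose transporter Slc2a5 fell by 3.13, from 11719 ± 667 to 1328 ± 181, the glucose transporter Slc2a2 fell by 2.80, the gluconeogenic Fbp1 fell by 3.34 and the sodium-glucose transporter Slc5a1 fell by 0.33. The adjusted p was 5.84e-07, and adjusted p = 0.238 with an estimated correlation. Peptide and amino acid handling went the other way, with 10 of 13 genes higher and 1 lower (10 and 1 adjusted over the list alone). The brush border protease Mep1a rose by 3.60, the glutamate transporter Slc1a1 by 3.22 and the dipeptidyl peptidase Dpp4 by 1.05, whereas the amino acid exchanger Slc7a8 fell by 0.55. That list rose with an adjusted p = 0.000552, and adjusted p = 0.238 with an estimated correlation.

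Xenobiotic metabolism was lower in SI3 in 14 of 16 genes and higher in 2 (14 and 2 adjusted over the list alone). The cytochromes Cyp1a1 and Cyp2c29 fell by 4.61 and fell by 4.50 and the glutathione transferase Gsta4 fell by 3.23, while the drug exporter Abcb1a rose by 1.06 and Cyp2c55 by 0.61. The adjusted p was 8.64e-08, and adjusted p = 0.238 with an estimated correlation. Of 15 genes for bile acid and sterol transport, 9 rose and 3 fell (9 and 3 adjusted over the list alone). The basolateral exporters Slc51a and Slc51b rose by 1.63 and 1.65 and the bile acid receptor Nr1h4 by 1.95, whereas its target Nr0b2 fell by 2.13, Abcc3 fell by 1.75 and Abcc2 fell by 1.61. That list rose with an adjusted p = 0.0402, and adjusted p = 0.238 with an estimated correlation; without the HF-PO pool its adjusted p was 0.0682.

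Cholesterol synthesis was higher in SI3 in 15 of 20 genes and lower in 2 (17 and 3 adjusted over the list alone). Sqle, which makes the sterol precursor squalene epoxide, rose by 2.05, from 1012 ± 234 to 4173 ± 263, Fdft1 rose by 1.30 and Hmgcs1 by 0.73, while the regulator Insig1 fell by 1.31 and Dhcr7 fell by 0.39. The adjusted p was 0.000821, and adjusted p = 0.392 with an estimated correlation. Fatty acid synthesis did not pass as a list (adjusted p = 0.283), with 8 of 13 genes higher and 4 lower (8 and 4 adjusted over the list alone). The desaturases Scd2 and Scd1 rose by 3.46 and 2.21, and the malic enzyme Me1 fell by 2.54.

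The markers of each end followed their names. Of 11 proximal markers 10 fell (10 adjusted over the list alone), among them the iron exporter Slc40a1 by -3.16, the ferric reductase Cybrd1 by -3.68 and the transcription factor Gata4 by -1.79, and the hormone gene Sct rose by 0.45. All 10 distal markers rose (10 adjusted over the list alone), among them the hormone genes Nts by 3.27 and Pyy by 2.52, Guca2a by 3.17 and the vitamin B12 receptor Cubn by 2.44. The adjusted p-values were 3.76e-07 for proximal markers and 2.6e-08 for distal ones. They became adjusted p = 0.238 and adjusted p = 0.0928 with an estimated correlation.

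Epithelial host defence was higher in SI3 in 8 of 9 genes and lower in 1 (8 and 1 adjusted over the list alone). The secreted lectin Reg3g rose by 3.44, from 3307 ± 313 to 35904 ± 1008, and the angiogenin Ang4 by 2.76, while Reg3a fell by 0.49. The adjusted p was 2.83e-05, and adjusted p = 0.238 with an estimated correlation. Interferon response genes were lower, with 14 of 17 past the threshold and 0 higher (16 lower adjusted over the list alone). The antiviral Rsad2 fell by 2.52, Usp18 by -2.42 and Ifit1 fell by 2.13, and Irf7 (-0.10), Mx1 (-0.31) and Ddx58 (-0.28) did not pass. That list fell with an adjusted p = 1.32e-08, and adjusted p = 0.238 with an estimated correlation.

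MHC class II genes, which present antigen, were higher in 4 of 6 (4 adjusted over the list alone), with Cd74 up by 0.54 and H2-DMa by 0.64. The adjusted p was 0.0399, and adjusted p = 0.364 with an estimated correlation; without the HF-PO pool it was 0.108. Cell cycle genes were higher in 16 of 20 and lower in 1 (16 and 1 adjusted over the list alone), with Ccna2 up by 1.15, the proliferation marker Mki67 by 0.64 and Rrm2 changed by -0.51. That list rose with an adjusted p = 0.00203, and adjusted p = 0.579 with an estimated correlation.

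**Figure D1:**
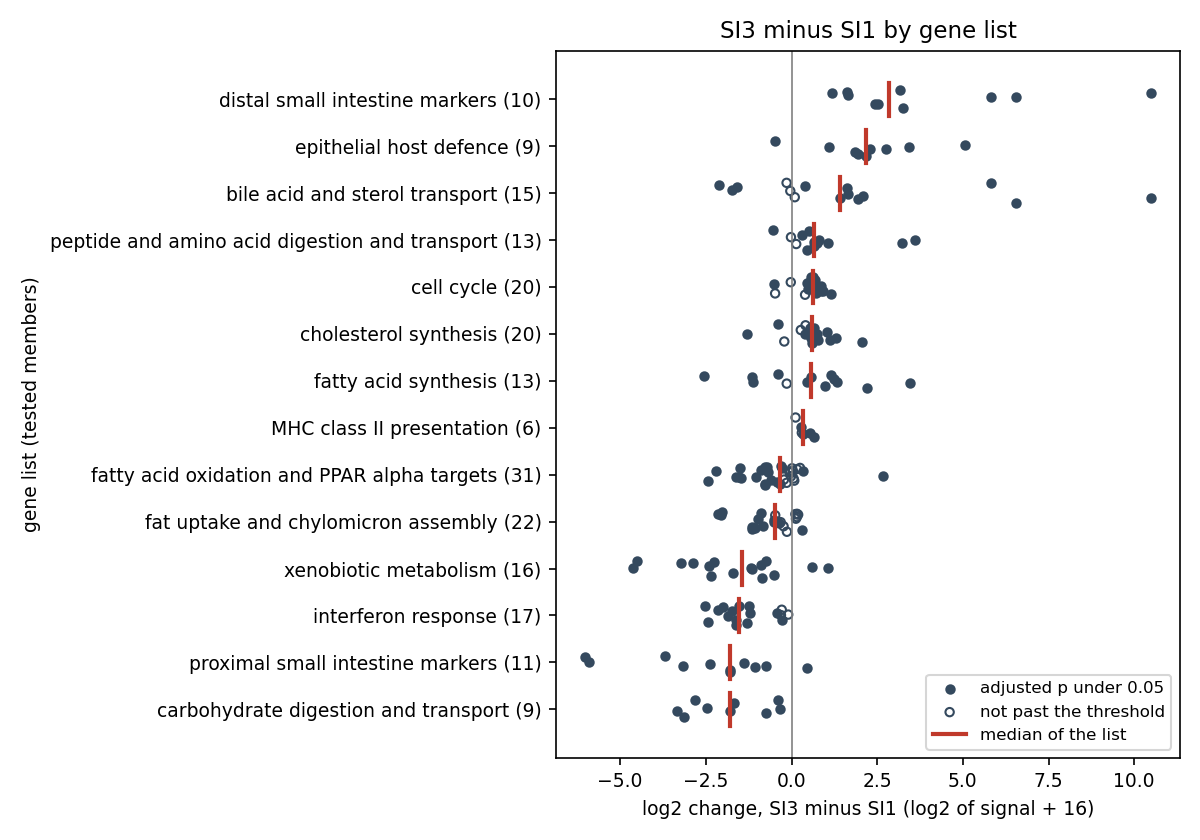
Each point is a gene of a pathway list at its log2 change in SI3 minus SI1 (x axis), by list (y axis), filled where its adjusted p is under 0.05, and the red bar is the list median. Medians lie at -0.49 for fat uptake and -0.34 for fatty acid oxidation, and at 2.84 for distal markers.

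Among cell types, markers of goblet and Paneth cells were higher in SI3. Goblet cell markers rose in 7 of 8 (7 adjusted over the list alone), the mucin Muc2 by 1.19 and Agr2 by 1.31, with an adjusted p = 0.000648, and adjusted p = 0.238 with an estimated correlation. Paneth cell markers rose in 4 of 4 (4 adjusted over the list alone), Mmp7 by 2.49, with an adjusted p = 0.000978, and adjusted p = 0.306 with an estimated correlation. Markers of T and intraepithelial lymphocytes fell in 6 of 6 (6 adjusted over the list alone), the granzyme Gzmb by -1.62 and the chemokine Ccl5 by -1.64, with an adjusted p = 5.06e-05, and adjusted p = 0.128 with an estimated correlation. Macrophage markers fell in 5 of 6 and rose in 1 (5 and 1 adjusted over the list alone), with Csf1r at -2.00 and Lyz2 at 0.70, an adjusted p = 0.00100, and adjusted p = 0.238 with an estimated correlation. Smooth muscle markers fell in 2 of 8 (2 adjusted over the list alone), Tagln by -0.58 and Acta2 by -0.44, with an adjusted p = 0.0251, adjusted p = 0.392 with an estimated correlation and 0.0575 without the HF-PO pool.

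Transcripts of the exocrine pancreas were abundant in SI1 beside the proximal gene groups. In SI3, 10 of the 11 were lower (10 adjusted over the list alone), with a median of -5.57 and an adjusted p = 2.61e-09, and adjusted p = 0.128 with an estimated correlation. Cel fell by 5.38 and Prss2 fell by 5.57. Clps, the colipase gene, did not pass (0.04), at 4007 ± 602 in SI1 and 4169 ± 923 in SI3.

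The other cell type lists did not pass. Enterocyte markers (adjusted p = 0.668) had Anpep up by 0.64 and Alpi changed by -0.61 of 5 genes. Enteroendocrine markers (adjusted p = 0.668) had 4 of 11 higher and 5 lower, with Cck at -2.37 and Gip at -1.80, and their median of 0.15 and mean of 0.12 were positive where camera's direction was down. Tuft cell markers (adjusted p = 0.834) had a median of -0.07 and a mean of 0.07, with Dclk1 up by 0.45 over all genes and 0 of 5 past the threshold when adjusted over the list alone. Stem cell markers (adjusted p = 0.494) had 3 of 5 higher, among them Olfm4 by 0.62 and Smoc2 by 0.70, and Rnf43 lower at -0.54, while Lgr5 (0.12) did not pass. Adipocyte markers (adjusted p = 0.779) had Adipoq at 2.69 and Cidec at -1.43 of 3 genes. Markers of B and plasma cells (adjusted p = 0.834) had 4 of 7 higher, with Ms4a1 at 1.62, and 2 lower, with Jchain at -1.44, where 3 were lower when adjusted over the list alone. Follicle-associated epithelium (adjusted p = 0.63) had Spib at 0.56 and Gp2 at -1.54 of 4 genes. Except where stated, the counts were the same when adjusted over the list alone. Mast cell and erythrocyte lists had fewer than 3 tested genes. In all, 19 of 27 lists passed with the preset correlation, and 0 of them with an estimated one.

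The comparison of SI2 with SI1 asked which of these differences appear by the middle of the intestine. Plb1 rose by 6.69 (SE 0.16), from 12.3 ± 5.86 to 2879 ± 376 (SD, n = 3 pools), Slc5a8 by 5.51, Fabp6 by 5.46, Gsdmc2 by 3.66 and Mgat4c by 3.30. Akp3 fell by 7.28 (SE 0.11), to 131.9 ± 12.3, and S100g fell by 7.07. The pancreatic enzyme genes Cpa1, Cela2a and Cpb1 changed by -7.78, -7.64 and -7.29, with 10 of the 11 pancreas markers lower in SI2. Limma's adjusted p-values of these genes lay between 5.38e-07 and 0.00015. Of all probe sets tested, 3375 (15.0%) differed, 1817 higher in SI2 and 1558 lower, with at least 2-fold changes in 195 and 254. Of 22 fat uptake genes, 3 rose by SI2, Cd36 by 0.71 (adjusted p = 0.0137), and 0 fell. Fatty acid oxidation had 2 of 31 higher and 3 lower, and cholesterol synthesis 1 of 20 higher and 3 lower. Host defence genes rose in 8 of 9, Reg3g by 2.70, interferon response genes fell in 11 of 17, and 3 of 6 MHC class II genes fell, H2-Ab1 by -0.54. Without the HF-PO, HF-OO or HF-SO pool, 811, 537 or 628 probe sets passed, and without the SI1 array of HF-PO 1949, a test added after the data were seen.

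The comparison of SI3 with SI2 asked which genes differ between the middle and the distal part, whether or not they had changed by SI2. Slc10a2 rose by 5.15 (SE 0.41), from 45.6 ± 42.4 to 1749 ± 139 (SD, n = 3 pools), Fabp6 by 5.04, Fgf15 by 4.88, Saa1 by 4.45 and Suox, the sulfite oxidase, by 3.60, from 695.6 ± 76.2 to 8627 ± 693. Bbox1, the last enzyme of carnitine synthesis, fell by 4.37 (SE 0.39), from 1418 ± 215 to 68.2 ± 56.6, Onecut2 fell by 4.13, Reg1 fell by 3.64, Cyp2c29 fell by 3.30 and Dnah2 fell by 3.09. Limma's adjusted p-values of these genes lay between 4.8e-05 and 0.00103. Of the probe sets tested, 4787 (21.3%) differed, 2352 higher in SI3 and 2435 lower, with at least 2-fold changes in 255 and 565. Fat uptake genes fell in 11 of 22 and rose in 0, Cd36 by -2.77, and fatty acid oxidation genes fell in 17 of 31 and rose in 2. Cholesterol synthesis genes rose in 13 of 20 and fell in 1, MHC class II genes rose in 5 of 6, and 12 of 16 xenobiotic genes fell. The HF-PO, HF-OO or HF-SO pool left out gave 2394, 1317 or 1714 probe sets.

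Over all 3 segments, 9154 probe sets (40.7%) differed by the F test. Of 1405 that differed at both steps, 1127 moved in the same direction at each and 278 turned. The iron exporter Slc40a1 was among those that turned, at 13073 ± 1391 in SI1, 334 ± 20.8 in SI2 and 1445 ± 158 in SI3. Without the HF-PO pool 5769 passed, without HF-OO 3680 and without HF-SO 4649.

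The comparison of diets asked whether mice on palm oil, the most saturated fat here, express more genes for handling fat in the distal intestine. Each diet had 1 array per segment, so no difference between diets has a replicate check, and the values describe these arrays. In SI3 the fatty acid carrier Fabp1 had a signal of 37792 with HF-PO against 17101 with HF-OO and 14700 with HF-SO. Apoc2 stood at 19985 against 7921 and 4790, Slc27a2 at 2303 against 1159 and 1198, Cd36 at 674.5 against 405.6 and 382.9, and Apoc3 at 16202 against 10602 and 10239. Apob, at 4884 against 6064 and 4823, and Fabp2 were not higher with HF-PO. The list for fat uptake and chylomicron assembly had a median log2 difference of 0.33, at the 100th percentile of random lists, and 18 of its 22 genes were above both other diets, where 7.33 would be if the 3 arrays were exchangeable. By at least 1.5-fold, 5 of the 22 were above both. In SI1 its median was -0.08 (percentile 49.5), or 0.02 after quantile normalization, and in SI2 it was 0.02 (41.9).

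Fatty acid oxidation genes were higher with HF-PO in all 3 segments, with medians of 0.14, 0.16 and 0.36 from SI1 to SI3, each at the 100th percentile. Of the 31 genes, 24, 27 and 30 were above both other diets, where 10.3 would be if the arrays were exchangeable. Most of these differences were small, and 3, 1 and 5 genes were above both by at least 1.5-fold. In SI3 Acaa1b stood at 2799 against 643.9 with HF-OO and 671.2 with HF-SO, Pdk4 at 663.9 against 158.9 and 126.0, Angptl4 at 1127 against 648.6 and 605.5, and Acot1 at 175.9 against 82.1 and 103.0. Cpt1a, the entry enzyme of mitochondrial oxidation, differed by 0.01 from the mean of the others. In SI1 Acot1 stood at 760.6 against 320.4 and 229.4.

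**Figure D2:**
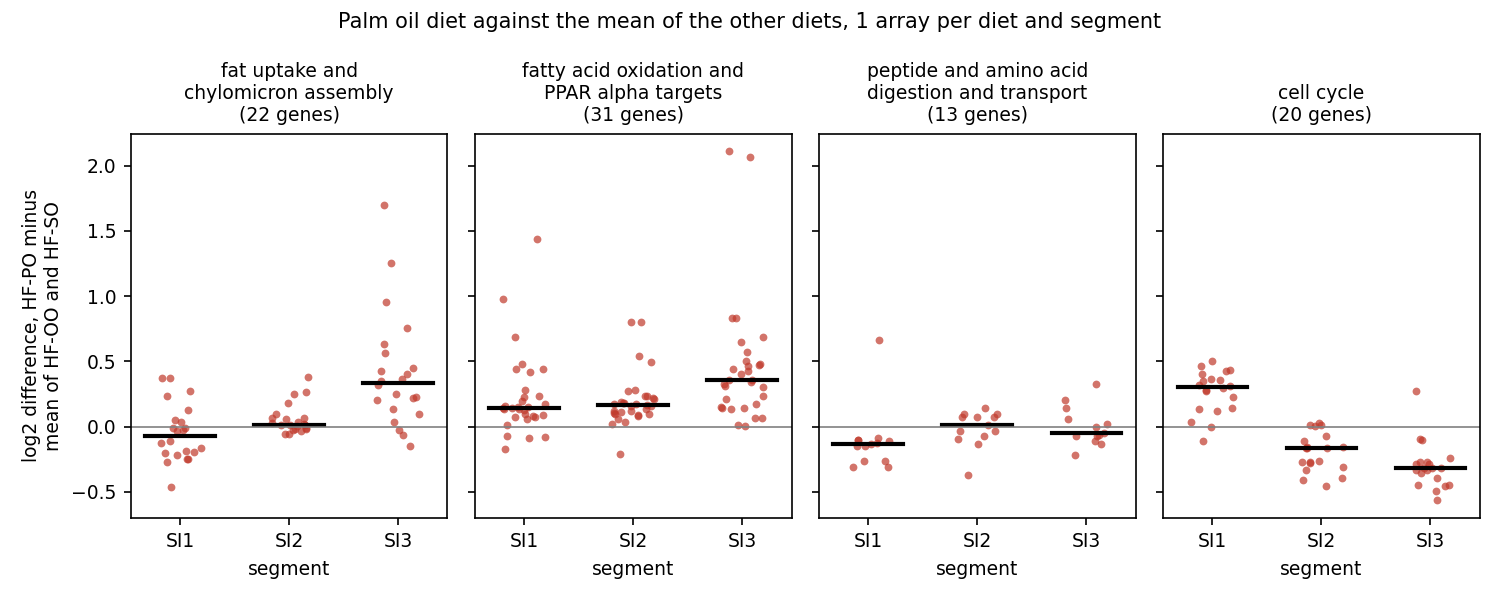
Each point is a gene, the y axis is its log2 signal with HF-PO minus the mean of HF-OO and HF-SO, the x axis is the segment, and the black bar is the list median, over 1 array per diet and segment. Fat uptake medians are -0.08, 0.02 and 0.33 from SI1 to SI3 (0.02 in SI1 after quantile normalization), cell cycle medians 0.31, -0.17 and -0.32, and peptide medians -0.14, 0.01 and -0.05 (0.04 in SI3 with arrays centred on their medians).

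In SI3, 571 probe sets were set apart with HF-PO, 200 higher and 371 lower, against 388 with HF-OO and 369 with HF-SO. The balance depended on scaling, since 323 were higher and 255 lower with arrays centred on their medians. Among the higher genes Acaa1b had a gap of 2.03, Pdk4 1.96, the desaturase Scd1 1.76, H2-Q10 1.75, the retinol saturase Retsat 1.53, Apoc2 1.33, Me1 1.29 and the retinol carrier Rbp2 1.25. Retsat stood at 5205 against 1796 and 1733, and Rbp2 at 22810 against 9566 and 8022. Ccdc114 and Onecut2 were also above, at weak signals of 88.3 and 70.9, where the gap depends on the pseudocount: that of Ccdc114 was 1.97, or 2.94 with a pseudocount of 1 and 1.03 with 64. The carbonic anhydrase Car1 was lower, at 77.3 against 1292 and 1026, a gap of -3.48. Cyp1a1, Slfn9, Tmem178, Zfp420, Mark1, Gng4, Col4a6, Pam and Bvht were lower at weak signals of at most 321.9 in SI3, and their gaps also depend on the pseudocount, as for Cyp1a1 with -2.23, or -3.89 with a pseudocount of 1 and -1.07 with 64. Cell cycle genes were lower, with a median of -0.32 (percentile 0.00) and 19 of 20 below both other diets, 0 of them by at least 1.5-fold. Paneth markers had a median of -0.39 (percentile 0.00) over 4 genes. Proximal markers (0.24), carbohydrate genes (0.25), interferon response (0.21) and T cell markers (0.37) were higher by their medians, each past the 99th percentile, with means of 0.41, 0.36, 0.23 and 0.20. Among the T cell markers Cd3e did not follow, at 51.8 against 205.4 with HF-OO and 50.7 with HF-SO, while distal markers differed by 0.02 (percentile 58.3). Adipocyte markers were above both other diets in 3 of 3 genes (0.42, percentile 99.6), with Cidec at 1181 against 658.3 and 667.0 and Adipoq at 311.0 against 269.8 and 307.3.

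In SI1, 417 probe sets were set apart with HF-PO, 141 higher and 276 lower, against 296 with HF-OO and 452 with HF-SO. The gastrokine Gkn2, a secreted peptide of stomach mucosa, stood at 2515 against 357 and 342.5, with a gap of 2.76, its relative Gkn3 had a gap of 2.24 and the stomach trefoil peptide Tff1 one of 1.14. Scd1 stood at 862.4 against 306.2 and 161.3, a gap of 1.45, and Acot1 had a gap of 1.21. Wbp2nl (2.19), Esco2 (1.47), Gins2 (1.26), Ajuba (1.05) and Kif20b (1.03) were the other genes most above. Cybrd1, the duodenal ferric reductase, stood at 435.4 against 2083 and 1209, a gap of -1.44. Cbln1 (-1.91), Slc7a5 (-1.75), Hrct1 (-1.69), Ubxn11 (-1.48), Scrt1 (-1.46), Htr1b (-1.37), Fcer2a (-1.34), Tbc1d2 (-1.26) and Il1f10 (-1.23) were also lower, at weak signals of at most 302.7, and 7 of the 20 gaps in SI1 moved by over 1.5 times with a pseudocount of 1 or 64. Beside these, exocrine pancreas transcripts were higher with HF-PO in 11 of 11 genes (median 0.36, percentile 100), host defence had a median of 0.29, Paneth markers 0.30 and cell cycle genes 0.31, with 17 of 20 above both, 0 of them by at least 1.5-fold. T cell markers were above both other diets in 6 of 6 genes (0.24, percentile 99.5). Enterocyte markers were lower in the same array, below both other diets in 5 of 5 genes (median -0.24, percentile 1.73), as were xenobiotic genes (-0.20, percentile 0.03), proximal markers (-0.18, percentile 0.56) and peptide genes, with 10 of 13 below both (-0.14, percentile 5.4).

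In SI2, 362 probe sets were set apart with HF-PO, 93 higher and 269 lower, against 439 with HF-OO and 313 with HF-SO. Scd1 stood at 2910 against 1282 and 473.7, a gap of 1.17. Lpcat4 (1.65), the pancreatic protease Ctrl (1.61), H2-Q5 (1.46), Ano1 (1.11), H2-T18 (1.10), Neil3 (0.98), Crygf (0.96), Mettl14 (0.92) and Sdr42e1 (0.89) were the others most above. The bile acid importer Slc10a2 stood at 3.2 against 45.7 and 88.0, a gap of -1.68, or -0.71 with a pseudocount of 64, and Bco1 at 441.7 against 1497 and 1186, a gap of -1.39. Orc1 (-2.10), Trmt61a (-2.10), Castor1 (-2.01), Appbp2os (-1.72), Golga7b (-1.51), Adm (-1.48), Sez6 (-1.40) and Ccbe1 (-1.39) were lower at weak signals, and 8 of the 20 gaps in SI2 moved by over 1.5 times with a pseudocount of 1 or 64. Carbohydrate genes (0.23) and T cell markers (0.42) were higher, both at the 100th percentile, interferon response had a median of 0.21 (percentile 99.99), and adipocyte markers were higher in 3 of 3 genes (0.36, percentile 99.6). Smooth muscle markers (-0.41, percentile 0.00) and xenobiotic genes (-0.11, percentile 0.14) were lower.

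Few genes were set apart with HF-PO in all 3 segments, 8 probe sets higher and 5 lower, of which 5 and 3 genes have a name here. Scd1, which makes monounsaturated fatty acids, had gaps of 1.45, 1.17 and 1.76 from SI1 to SI3, and Acaa1b 0.62, 0.61 and 2.03. Gkn2 had gaps of 2.76, 0.68 and 0.86, Me1 0.91, 0.69 and 0.74, and Prkar1b 1.33, 0.72 and 1.40. Me1 and Prkar1b were each read from a probe set other than the gene's brightest. The brightest probe set of Me1 had gaps of 0.51, 0.50 and 1.29, so it passed the 1.5-fold limit in SI3 only. Signals of Gkn2 in SI2 were weak, at 49 with HF-PO against 24.6 with HF-OO and 22.7 with HF-SO. In SI3 they were 67.1 against 20.5 and 29.8. All of these lay below the median signals of the arrays, 94.4 to 105.9, so the gaps of Gkn2 in SI2 and SI3 depend on the pseudocount. Bco1, which cleaves beta-carotene into vitamin A, was lower by gaps of -1.22, -1.39 and -1.02, the glucocorticoid-induced Fkbp5 by -0.96, -0.82 and -0.87, and Rad54l2 by -0.70, -0.70 and -0.62. With HF-OO the circadian repressor Ciart was higher in all 3 (0.72, 0.69 and 1.03). With HF-SO the desaturase Scd2 (-0.91, -1.57 and -0.92) and the gluconeogenic Pck1 (-0.61, -0.81 and -0.68) were lower in all 3. Across genes, which are not independent replicates, the differences of HF-PO from the others correlated with r = 0.051 between SI1 and SI2, 0.004 between SI1 and SI3 and 0.156 between SI2 and SI3, where HF-SO had 0.147 and HF-OO 0.057.

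**Figure D3:**
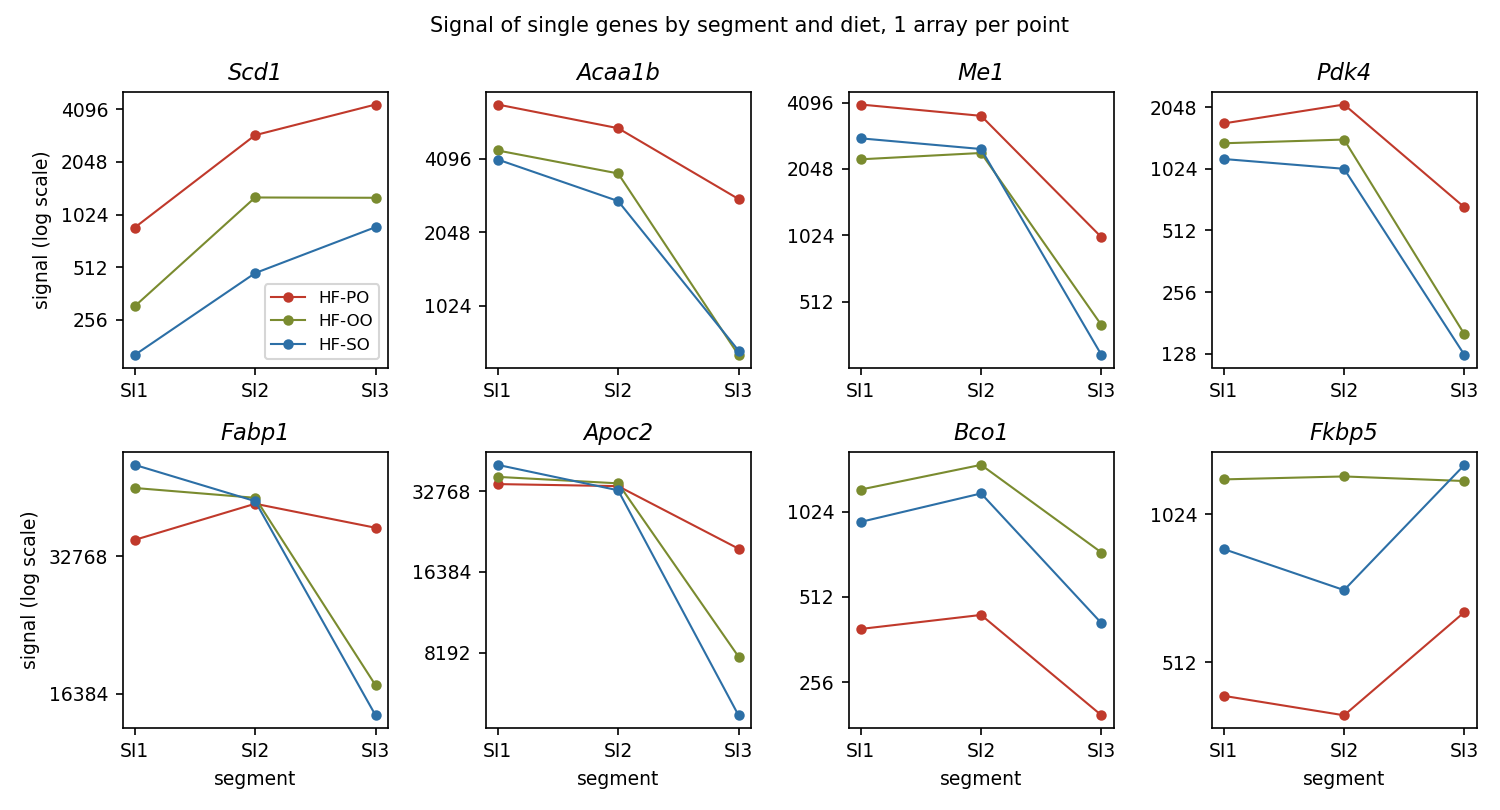
Signal on a log scale (y axis) by segment (x axis) for 8 genes, with a line per diet and 1 array per point. In SI3 the HF-PO point of Fabp1 is at 37792 against 17101 and 14700, and the HF-PO points of Scd1 lie above and those of Bco1 below both other diets in all 3 segments.

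With HF-OO, the cholesterol exporter Abca1 was higher in SI1, at 2691 against 949.5 with HF-PO and 940.4 with HF-SO. Mbl2 (1.83), H2-T18 (1.73), Chac1 (1.14) and 4833439F03Rik (1.02) were also above there, and Fbf1 (-2.03), Acadsb (-1.69), Cphx3 (-1.65), Stra6 (-1.64) and Depp1 (-1.57) below. In SI2 Tmem151a (2.08), Car1 (1.89), Sytl1 (1.45), Rps27 (1.31) and Nrip2 (1.23) were above, and Mroh2a (-2.09), Hs3st2 (-2.04), Zap70 (-2.00), Vezt (-1.83) and Rnf150 (-1.80) below. In SI3 Cd3e (1.71), Lyrm9 (1.56), Sema3f (1.41), Pnmt (1.31) and Drp2 (1.16) were above, and Zap70 (-2.52), Sirt4 (-2.39), Arhgef25 (-2.25), Lect2 (-2.23) and Prss2 (-1.86) below. The T cell kinase gene Zap70 stood at 109.5 in SI3 against 703.6 and 1033. Of the 30 gaps with HF-OO, 12 moved by over 1.5 times with a pseudocount of 1 or 64, among them Lect2 (-1.20 with 64), Sirt4 (-1.43) and Prss2 (-1.11), whose signals with HF-OO were 10.2, 16.2 and 21.8.

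With HF-SO, Hk3 (2.02), 3110021A11Rik (1.65), Cphx3 (1.19), Zdhhc15 (1.12) and Fa2h (1.00) were higher in SI1, and Osbpl5 (-2.08), Depdc1b (-1.73), Diras1 (-1.61), Mcat (-1.39) and Ttc38 (-1.39) lower. In SI2 Tbc1d2 (2.05), Impdh1 (1.85), Orc6 (1.22), Khsrp (1.18) and Cyp39a1 (1.00) were higher, and Msx1 (-2.45), Car1 (-1.84), Scd2 (-1.57), Ctrb1 (-1.42) and Scd1 (-1.41) lower. In SI3 the carboxylesterase Ces5a stood at 1231 against 472.9 with HF-PO and 290.4 with HF-OO, with Fli1 (1.28), 9330133O14Rik (1.24), Zbp1 (1.08) and Gm3764 (1.05) also above. Dhx38 (-2.29), Nwd1 (-2.07), Kcnk10 (-1.98), Wbp2nl (-1.88) and 1810064F22Rik (-1.82) were lower there. Of the 30 gaps with HF-SO, 14 moved by over 1.5 times with a pseudocount of 1 or 64, among them in SI2 Msx1 (-1.40 with 64), Car1 (-0.88) and Ctrb1 (-0.63), whose signals with HF-SO were 11.8, 7.3 and 7.4. Against HF-OO, HF-SO had cholesterol synthesis genes at 0.24 in SI1 (percentile 100) and -0.16 in SI3 (0.02), carbohydrate genes at -0.32 in SI2 (0.00), fatty acid synthesis at -0.19 in SI3 (0.06) and fat uptake genes at -0.12 in SI3 (0.25). Higher in SI3 were xenobiotic genes (0.15, percentile 100) and T cell markers (0.34, percentile 99.99, with a mean of 0.028). Also past the 99th percentile were interferon response in SI1 (0.24), smooth muscle (0.29) and B cell markers (0.42) in SI2, and B cell (0.30) and macrophage markers (0.18) in SI3. Below the 1st were peptide genes in SI1 (-0.097) and SI2 (-0.14), bile acid transport (-0.16) and pancreas markers (-0.25) in SI2, and interferon response (-0.19) and proximal markers (-0.16) in SI3.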

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

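The results here were picked because the median of a gene list lay among the highest 2.5 percent of random lists in one segment and among the lowest 2.5 percent in another, with opposite signs, and these limits were not fixed before the data were examined. With 1 array per diet and segment none of the differences was tested, random lists ignore that genes of a list move together, and 5 percent of lists would lie past the limits in a segment by chance. Cell cycle genes in HF-PO, against the mean of the other diets, had a median log2 difference of 0.31 in SI1, -0.17 in SI2 and -0.32 in SI3, so SI2 differed from SI1 by -0.47 and SI3 from SI1 by -0.62. Paneth cell markers, 4 genes, went from 0.30 in SI1 to -0.23 in SI2 and -0.39 in SI3, which is -0.53 and -0.69. Proximal markers in HF-PO went from -0.18 in SI1 to 0.24 in SI3, a difference of 0.42. Between HF-SO and HF-OO, cholesterol synthesis genes went from 0.24 in SI1 to -0.16 in SI3, a difference of -0.40, and interferon response genes from 0.24 to -0.19, a difference of -0.43. No explanation of the cell cycle, Paneth, cholesterol or interferon differences was tested.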

How the results depend on the processing

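Of the alternatives, only those that leave out the HF-PO array of SI1 or of SI3 and those that set HF-PO against HF-OO alone or HF-SO alone were added after the data were seen. The 44 segment results for named genes kept their direction and their side of the threshold in 543 of 543 recomputations, and of 162 for gene lists along the gut 140 did so, 22 lost their call and 0 reversed. The named genes were picked as the largest changes past the threshold, so their stability says little about other genes. Recomputations in which a probe set failed the expression filter of the setting were left out. Cpa1, Cpb1 and Slc10a2 dropped out in this way with a pseudocount of 1. With an estimated correlation 0 lists passed, which removes the assumption of near independence that the preset value makes; with a pool left out 16 to 19 passed.

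Segment counts stayed within 1.5 times the reported ones in 42 of 61 recomputations and were lower in 19. A 2-fold requirement, stricter by construction, gave 2090 probe sets for SI3 against SI1, 449 for SI2 against SI1 and 820 for SI3 against SI2. With no expression filter, which adds the weaker probe sets to those tested, 604 passed for SI2 against SI1, 1681 for SI3 against SI2 and 4666 for any segment; the cause was not tested. Without the diet pool as a block the counts were 10178, 3823, 5136 and 9716 for SI3 against SI1, SI2 against SI1, SI3 against SI2 and any segment, so the pairing changed none of them by as much as 1.5 times. Leaving out a pool or an array, with fewer samples, gave 5551 to 8583 for SI3 against SI1, 537 to 3064 for SI2 against SI1, 1317 to 4814 for SI3 against SI2 and 3680 to 7736 for any segment. The lowest count came without the HF-OO pool each time. For SI2 against SI1, leaving out the HF-PO pool, HF-OO pool, HF-SO pool or the SI1 array of HF-PO gave 811, 537, 628 and 1949. For SI3 against SI2 the pools in that order gave 2394, 1317 and 1714, and for any segment 5769, 3680 and 4649. For SI3 against SI1, HF-OO and HF-SO left out gave 5551 and 6478.

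Counts of probe sets set apart in HF-PO stayed within 1.5 times in 17 of 42 recomputations and moved in 25. A pseudocount of 64, which shrinks differences at weak signals, gave 77 higher and 124 lower in SI1, 54 and 130 in SI2, and 121 and 170 in SI3. With no filter, so more weak probe sets, they were 1558 and 2519, 1782 and 2159, and 1722 and 2745. A filter that kept the brightest probe sets left 18 and 21, 18 and 37, and 91 and 31, so that in SI3 more were higher than lower. A 2-fold threshold left 21 and 53, 12 and 50, and 39 and 70. Centring arrays on their medians gave 323 higher in SI3. There the HF-PO array had the lowest median of log2(signal + 16), 6.787 against 6.86 with HF-OO and 6.879 with HF-SO. Centring therefore raised all its values against theirs. In SI3, HF-PO had more probe sets set apart than either other diet under each of these settings.

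Diet lists shifted by at most the SD of the random lists' medians in 637 of 792 recomputations. Another 152 moved more and 3 were counted as reversed. The 3 are not all the changes of sign. From a main median of -0.08, fat uptake in SI1 turned positive with quantile normalization. From 0.02 in SI2 it turned negative against HF-OO alone, and peptide genes in SI3 turned positive with centred arrays. Fat uptake in SI3 had medians of 0.28 with quantile normalization, 0.41 with centred arrays and 0.25 against HF-OO alone, and a mean of 0.41. In SI1 it had 0.021 with quantile normalization, -0.026 with centred arrays and -0.034 against HF-OO alone, and in SI2 0.061 with centred arrays, a mean of 0.057, -0.012 against HF-OO alone and 0.054 against HF-SO alone. Fatty acid oxidation had 0.19, 0.21 and 0.44 from SI1 to SI3 with centred arrays. The HF-PO array had the lowest median of each segment, so centring raised its values. The means of this list were 0.23, 0.20 and 0.46, and against HF-OO alone SI3 had 0.32. The cause of these last differences was not tested. Epithelial host defence in SI2 reversed to -0.0194 with the stricter filter and to -0.0192 against HF-SO alone, as did B and plasma cell markers in SI2 against HF-SO alone (-0.0215); the cause was not tested. Of 615 recomputations for named genes of the diets, 551 shifted the gap by at most the gene's residual SD in the segment model. Another 64 moved more and 0 reversed. That SD is wide for some genes, as for Car1, lower with HF-SO in SI2, with an SD of 1.33. Its gap of -1.84 became -3.05 with a pseudocount of 1 and -0.88 with 64. Recomputations in which a probe set failed the expression filter of the setting were left out. Both weak signals and having 1 array per group limit the diet values. In simulated arrays with the empirical Bayes residual SD of the segment model, 211 probe sets that had not been changed were set apart in HF-PO of SI3. That SD leaves out differences between pools that the segments share, so 211 may be too low. The simulation set 215 and 207 apart with HF-OO and HF-SO, against 388 and 369 in the real arrays of SI3.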

Other observations

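All tests of explanations here were chosen after the result was seen, except the count of pools per diet and the counts of other splits of the arrays. The lists for stomach, clock, vitamin A and glucocorticoid genes were also added after the data were seen, and they hold genes that prompted them, so their percentiles partly restate those genes.

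Genes of vitamin A handling differed between diets in opposite directions. Bco1, which cleaves beta-carotene, had signals of 394.1, 441.7 and 195.3 with HF-PO from SI1 to SI3, against 1224, 1497 and 733.5 with HF-OO and 941, 1186 and 413 with HF-SO. Retsat stood at 9785 with HF-PO in SI1 against 7773 and 7540, and at 5205 in SI3 against 1796 and 1733. Over 10 genes of vitamin A handling, HF-PO minus the mean of the others had a median of -0.07 in SI1 (percentile 22.2), 0.05 in SI2 (78.7) and 0.22 in SI3 (99.8). Without Bco1, Retsat and Rbp2, which prompted the list, the other 7 had 0.14 in SI3 (95.9).

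Genes that glucocorticoids induce were lower with HF-PO in SI1. Fkbp5 stood there at 437.7 against 1204 with HF-OO and 869.5 with HF-SO, and the metallothioneins Mt1 at 4448 against 7754 and 6135 and Mt2 at 1611 against 3017 and 2968. Over 8 genes the median was -0.32 in SI1 (percentile 0.00), -0.13 in SI2 (1.76) and -0.09 in SI3 (6.5). From SI1 to SI3, 6, 4 and 4 of the 8 were below both other diets, and 1, 1 and 4 were above both. Without Fkbp5, which prompted the list, the other 7 had -0.27 (0.07), -0.093 (6.25) and 0.18 (98.8), so in SI3 the direction rests on that gene. With HF-OO the same genes had medians of 0.21, 0.21 and 0.03, or 0.13, 0.19 and 0.012 without Fkbp5.

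Fat uptake and fatty acid oxidation genes were higher with HF-PO in SI3, by a median of 0.35 over 53 genes, and at least 0.32 in 4 settings of scaling and pseudocount, so scaling is not the cause. Lists matched on the ratio of SI2 to SI3 signals had a median of 0.08 and at most 0.25, which leaves 0.26 beyond them. The match was in 20 bins of the ratio and not on brightness, so it cannot settle how much tissue of SI2 in that pool contributes. A contribution stays open, as 59 other genes much higher in SI2 point to a share of 8.90% (quartiles 3.88 and 16.2), and the 7 members no higher in SI2 had a median of 0.03. More enterocyte and less crypt material is not the whole cause, because 17 genes of the peptide and enterocyte lists, not all of them brush border genes, had a median 0.35 below the fat genes (their own quartiles -0.074 and 0.10). With the carbohydrate list, itself at 0.25, included, 26 genes had a median 0.26 below (quartiles -0.058 and 0.23). However, cell cycle genes (-0.32) and Paneth markers (-0.39) were lower and T cell markers higher (0.37) in that array. Adipose tissue, with only 3 adipocyte genes past the filter (median 0.42, Adipoq at 311.0 against 269.8 and 307.3), and a difference between pools that is not due to diet, with 1 pool per diet, cannot be told apart from an effect of palm oil, which stays untested.

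SI1 held transcripts that pancreas and stomach are known for. Exocrine pancreas in the SI1 pools would be consistent with the median change of -5.57 from SI1 to SI3 over 11 pancreas genes, although the labels say that pancreatic tissue was removed, and Clps did not follow. In the HF-PO array of SI1 the stomach surface genes were higher by a median of 2.48 over 5 genes, of which only 2, Gkn2 and Tff1, which prompted the list, passed the expression filter, with Gkn1 at 1321 against 258.3 and 193.6, Tff2 at 4474 against 374 and 693.3 and Muc5ac at 70.5 against 13.2 and 8.2. Stomach gland genes differed by a median of 0.39, with 1 of 6 past the expression filter and a highest signal of 135.2, so stomach mucosa with its glands and another source of the surface genes cannot be told apart. A different boundary of the first part, and an effect of diet on SI1, were not tested.

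Clock genes were higher with HF-OO. Over 10 output genes HF-OO had medians of 0.54, 0.42 and 0.31 above the other diets from SI1 to SI3, each at the 100th percentile (0.48, 0.39 and 0.28 without Ciart, which prompted the list), with Dbp at 3300 in SI1 against 2274 with HF-PO and 1710 with HF-SO and Ciart at 168.7 in SI3 against 66.8 and 74.4. A candidate explanation is that the HF-OO mice were killed at another time of day, which predicts that genes of the opposite phase are lower. Their medians over 4 genes were -0.07, -0.37 and -0.25, so the pair of lists moved apart in 3 of 3 segments, slightly in SI1 (percentile 30.5). An effect of olive oil on the clock stays open and untested.

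Other splits of the arrays were counted for the segment comparisons. For SI3 against SI1, a fit to the 6 arrays of those segments called 8486 probe sets, and the highest of the other splits called 0. For SI2 against SI1 the counts were 1941 and 0, and for SI3 against SI2 they were 4075 and 0. In each case 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. For all 3 segments, 1 of 36 relabellings within pools gave as many as the real 9154, and the highest other gave 1862. A share of 1 of 36 is under 0.05, the limit set before the data were seen, which argues against chance for all 3 segments together. The other relabellings and splits move segment differences into the residual. Their low counts therefore do not measure how far the real labels stand out, and for the pairs of segments chance was not excluded.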
